A study of Mus musculus with 4 samples.

How the data were processed

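Thymic iNKT cells of mice 6 to 8 weeks old, sorted as CD3+ and CD1d tetramer+ cells after magnetic enrichment, were profiled in 4 single-cell libraries, 2 WT and 2 ACC1 KO, per the labels. Libraries were made with the 10x Genomics Chromium 3′ kit, version 3.1, per the labels' protocols. The deposited values were counts of unique molecular identifiers (UMIs) for 32285 genes per barcode, made by the authors with Cell Ranger 7.0.0 on the mouse genome mm10, per the submitters' processing notes and the file headers. The lowest barcode in each library held 500 to 522 UMIs, as read from the values. The deleted part of Acaca, and whether each library came from a separate animal, are not given in the sources used here.

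All 30455 barcodes were read. A cell was kept with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs, which removed 42, 33, 146 and 67 barcodes from WT 1, WT 2, ACC1 KO 1 and ACC1 KO 2. Doublets were scored within each library against 2 simulated doublets per cell, and 0.8% of the cells per 1000 cells were removed, which came to 4.36, 7.91, 5.02 and 6.83%. The 28247 cells kept were clustered on 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1, giving 21 clusters. Values were scaled within each replicate number before clustering, a choice made after the data were seen, because unscaled clusters had split by number. Clusters were named from 14 marker sets fixed before the data were examined. The limits on the marker scores that decide a name, and the order of the names, were set after the data were seen. They were 2.5 for other cell types, iNKT17-like and iNKT0-like, 1.5 for cycling, 2.0 for interferon-responding and iNKT2-like, and -1 for iNKT1-like cells. A score was the mean of log2 CPM over the markers, with 5 added to the CPM, less the median over clusters. A marker counted above 5 CPM. The top 10 genes of every cluster, ranked by folds of CPM with 20 added, were checked against the marker sets. In that check 1 B cell-like cluster of 46 cells failed, as did 3 of the clusters from the WT libraries alone and 2 of those without genotype genes. Clusters of DP thymocyte-like, B cell-like and myeloid-like cells (608, 94, 344 and 162 cells) were left out, and 27039 iNKT cells in 15 clusters, 8 of them iNKT1-like, were used.

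UMIs were summed per library over all iNKT cells, and over each class with at least 50 cells in every library. The sums of all iNKT cells held 23.5, 63.1, 28.5 and 65.4 M UMIs, so that a gene at 1 CPM rests on 23.5 to 65.4 UMIs per library. Genotypes were compared with the edgeR quasi-likelihood F test (glmQLFit with robust spread, TMM factors, filterByExpr, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are those of the log2 fold changes, and fold changes within a number are differences of log2 CPM with a prior count of 2. Fold changes of genes with few WT UMIs are given as ratios of UMI shares with 95% counting intervals, and where the WT held none, 3 counts were taken as a floor. The class difference was tested on 8 sums, 2 classes in 4 libraries, with the library as a term. The same difference for iNKT17-like cells was not run, since 22 cells remained in ACC1 KO 1. Shares of classes were compared with the exact permutation test, and intervals per library are Clopper-Pearson. The 27 gene lists were tested with limma camera at its preset correlation of 0.01, on voom values, adjusted over the lists, and again with an estimated correlation and with fry. At the preset, camera compares members with the other genes, so its p-values rest on the spread between genes. With an estimated correlation it is limited to the few degrees of freedom of 4 libraries. A list then has little room to pass. Members of a list were also adjusted over the list alone.

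Genes are named by a rule fixed in advance: Acaca; up to 10 genes per direction (5 within a class) with the largest changes among those past the threshold, with a mean of at least 20 CPM and no overlap between genotypes; and up to 4 members of each list with the smallest p. Genes named outside the rule are said to be so, and some genes that the rule names are not reported here. The tests were tried on simulated counts with 200 changed genes drawn from the means and depths of these libraries. In iNKT1-like, iNKT2-like, cycling and interferon-responding cells they recovered 87.3, 96.8, 92.1 and 90.5% of genes changed 4-fold, and 40.9, 34.8, 46.2 and 42.4% of those changed 2-fold. For the class difference they recovered 53.1% at 4-fold and 7.5% at 2-fold.

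Alternatives changed 1 choice at a time: DESeq2 size factors or its Wald test, no filter on low counts or a mean of at least 10 CPM, every barcode, doublets kept, a mitochondrial limit of 5%, at least 1000 genes, resolutions of 0.5 and 2, cells thinned to 2000 UMIs (467 cells were too shallow), sums thinned to the smallest total, the same number of cells or the same mix of classes, clusters from the WT libraries alone, names from the highest marker mean, and each library left out in turn. A lone library in an arm was then assumed to vary like the other group. Scaling over all libraries together, clustering without 519 genes with an unadjusted p under 0.05 between genotypes in iNKT1-like cells, and leaving out interferon-responding cells were added after the data were seen. The 519 were of 13683 tested, a smaller share than chance alone gives at that threshold. The name genotype genes thus stands for the rule only. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.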

Results

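Single-cell RNA-seq libraries were made from thymic invariant natural killer T (iNKT) cells, T cells whose semi-invariant receptor recognises lipid antigens presented by CD1d. The cells came from mice 6 to 8 weeks old, were enriched on magnetic beads and were then sorted as CD3+ and CD1d tetramer+. There were 2 wild-type (WT) libraries and 2 libraries labelled ACC1 knockout (ACC1 KO), numbered 1 and 2 in each genotype. ACC1, encoded by Acaca, is the acetyl-CoA carboxylase that makes malonyl-CoA for fatty acid synthesis, and the series title names the survival of thymic iNKT cells as the subject. The deposited files held 5499 barcodes for WT 1, 9927 for WT 2, 6416 for ACC1 KO 1 and 8613 for ACC1 KO 2, with totals of 29.1, 72.8, 33.2 and 74.2 M UMIs. After quality filters, removal of doublets and removal of clusters of other cell types, 4611, 9017, 5611 and 7800 iNKT cells remained, with medians of 1933, 2229, 1811 and 2422 genes per cell. The 2 libraries numbered 1 carried the Y-linked gene Ddx3y, at 82.3 CPM in WT and 76.4 CPM in ACC1 KO, with Xist below 1 CPM. The 2 libraries numbered 2 carried Xist, at 590 CPM in WT and 655 CPM in ACC1 KO, with Ddx3y below 1 CPM, and they were also the deeper ones. Values within each number are therefore given beside the pooled ones. The labels do not say that the libraries came from separate animals, so p-values of single genes measure the spread between these 4 libraries. Within a genotype that spread includes the difference in sex and depth between the libraries numbered 1 and 2. The p-values of camera at its preset correlation compare list members with other genes. They measure the spread between genes and not that between libraries. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot give a p below 0.3333.

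The targeted gene was counted in every library. Acaca (ENSMUSG00000020532, chromosome 11, 84129672 to 84401651, plus strand, mm10) had 32.5 ± 0.303 CPM in the WT libraries and 54.8 ± 10.2 CPM in the libraries labelled ACC1 KO (mean ± SD, n = 2 each). The log2 fold change was 0.75 ± 0.17 (SE), with 0.54 in the libraries numbered 1 and 0.94 in those numbered 2. It did not pass adjustment over all genes (edgeR quasi-likelihood test, adjusted p = 0.641, DESeq2 adjusted p = 0.0578). With the replicate number as a block Acaca passed in edgeR, as given below with the dependence on processing. Within single iNKT classes the log2 fold change of Acaca was 0.80 in iNKT1-like, 0.98 in iNKT2-like, 0.59 in cycling and 0.90 in interferon-responding cells. None of these passed adjustment in edgeR without a block (the smallest adjusted p was 0.339), while DESeq2 gave an adjusted p of 0.0281 in iNKT1-like cells. These libraries count the 3′ ends of transcripts and the labels do not give the deleted part of the gene, so that counts of Acaca check nothing about the genotype labels.

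The first comparison was of all iNKT cells between genotypes. Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879, minus strand), a stearoyl-CoA desaturase that makes monounsaturated fatty acids, rose from 4 UMIs in the WT libraries to 1193 UMIs in the libraries labelled ACC1 KO. The ratio of its UMI shares was 275 (95% interval for counting error, 107 to 1012), and its adjusted p was 0.0296 (edgeR quasi-likelihood test, n = 2 libraries per genotype, higher in both ACC1 KO libraries). Scd1 was the 1 gene of 14727 tested that passed. Many more passed with the replicate number as a block, as given below with the dependence on processing. Scd1 is named as the single call, since its mean lies below the 20 CPM that the rule for named genes asks for. The test without a block gave 721 of the 14727 genes at an unadjusted p under 0.05, no larger a share than chance alone gives at that threshold. DESeq2 called 66 genes higher and 36 lower. Among the list members named below, Acsl3, Abcg1, Abca1, Hk2, Lpcat3, Gzmb, Aldoc, Pik3ip1 and Itga4 passed over all genes in DESeq2 and not in edgeR. In 2150 genes (14.6%) both ACC1 KO libraries lay above both WT libraries and in 2248 (15.3%) below. Chance gives 16.7% each way if the 4 libraries are exchangeable. Libraries of one number shared sex and depth, so chance may give less here. On simulated counts with the depths of these libraries, the test recovered 86.2% of genes changed 4-fold, 26.9% of those changed 2-fold and 4.5% of those changed 1.5-fold. Across the 14727 genes, the log2 fold changes of the libraries numbered 1 and of those numbered 2 had a Pearson correlation of 0.486, where genes are not independent replicates. Scd1 passed without each library in turn, but 12 genes passed without WT 1, 6 without WT 2, 3 without ACC1 KO 1 and 2 without ACC1 KO 2. No gene passed at a mean of at least 10 CPM, which leaves Scd1 out. Scd1 did not pass when every deposited barcode was summed, which brings back B cell-like cells that held 99.7 CPM of Scd1 in the WT and 163 CPM in the ACC1 KO libraries.

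Genes of fatty acid synthesis rose as a list in the libraries labelled ACC1 KO. Of its 21 measured members, 9 rose and none fell when adjusted over the list alone, and 1 (Scd1) passed over all genes. Both ACC1 KO libraries lay above both WT libraries in 15 members and below them in none, against 16.7% each way by chance for exchangeable libraries. Scd2, another stearoyl-CoA desaturase, went from 35.7 ± 7.36 to 239 ± 18.7 CPM (mean ± SD, n = 2 each), a log2 fold change of 2.75 ± 0.19 (SE) with 2.46 in number 1 and 3.05 in number 2. Fads2, the delta-6 desaturase of polyunsaturated fatty acid synthesis, had 3 UMIs in the WT and 444 in the ACC1 KO libraries, a ratio of 137 (95% counting interval, 46.4 to 665). Srebf1, which encodes the transcription factor SREBP1, went from 18.6 ± 1.44 to 61.9 ± 2.55 CPM, a log2 fold change of 1.74 ± 0.14 (SE). Over all genes the adjusted p was 0.083 for Scd2 and Fads2 and 0.101 for Srebf1 in edgeR's quasi-likelihood test, and 2.2e-33, 2.8e-10 and 2.2e-16 for Scd2, Fads2 and Srebf1 in DESeq2. The median log2 fold change of the list was 0.37, with 0.34 in number 1 and 0.43 in number 2. The list was called by camera (adjusted p = 2.3e-16), and not with an estimated correlation (adjusted p = 0.482 with an estimated correlation).

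Cholesterol synthesis genes and other targets of the transcription factor SREBP2 rose as a list as well. Adjusted over the list alone, 17 of 25 measured members rose and none fell, while none passed over all genes in edgeR and 10 did in DESeq2, among them the 3 named next. In 22 members both ACC1 KO libraries lay above both WT libraries, and in none below. Squalene epoxidase, Sqle, had a log2 fold change of 2.43 ± 0.24 (SE), the SREBP-retaining protein Insig1 of 1.62 ± 0.16 and lanosterol demethylase, Cyp51, of 1.35 ± 0.13, each adjusted over all genes to 0.187 by edgeR. The median over the list was 0.70, with 0.75 in number 1 and 0.77 in number 2. Camera called the list (adjusted p = 6.1e-30), an estimated correlation did not (adjusted p = 0.158 with an estimated correlation), and fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0471. The estimated correlation of the list was -0.022, below the preset 0.01. Its lost call thus came with the fewer degrees of freedom and not from correlated members.

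**Figure D1:**
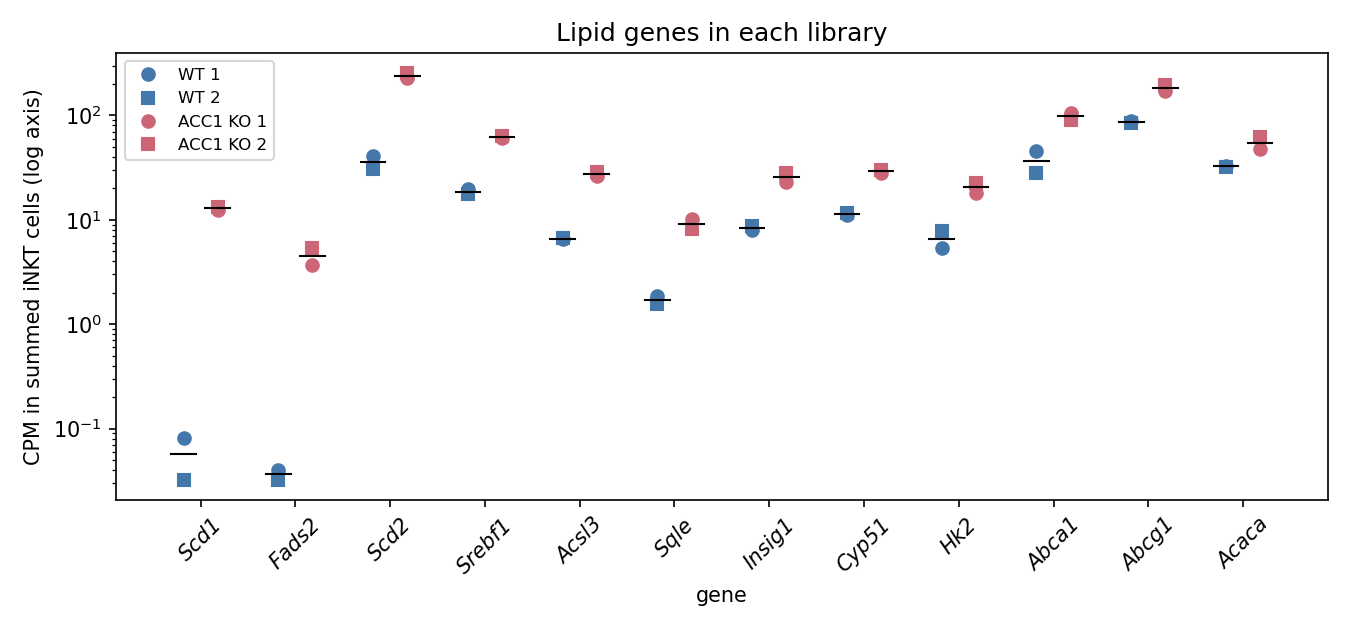
CPM (log axis) of 11 lipid and glucose genes and of Acaca in the summed iNKT cells of each library. Circles are libraries numbered 1, squares those numbered 2, blue is WT, red is ACC1 KO, and black lines are the means of 2 libraries; both red points lie above both blue points for every gene drawn, from Acaca (32.5 against 54.8 CPM) to Scd1 (0.0565 against 12.8 CPM).

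Among 20 measured genes of fatty acid uptake and lipid storage, 3 rose when adjusted over the list alone and none fell. They were Acsl3, a long-chain acyl-CoA synthetase, with a log2 fold change of 2.06 ± 0.14 (SE, edgeR adjusted p over all genes 0.083), and the sterol exporters Abcg1 and Abca1, at 1.07 ± 0.14 and 1.42 ± 0.26. Both of these exporters move lipid out of cells and do not take up fatty acids. The median over the list was 0.020, with 7 members above and 3 below the WT libraries without overlap and the other 10 overlapping, and Lpin1 stood at 0.48 ± 0.14. Camera called the list higher (adjusted p = 0.0026, and 0.497 with an estimated correlation). Genes of fatty acid oxidation had a median log2 fold change of -0.087 and were not called (adjusted p = 0.0655), but were called lower with the same mix of classes (0.0197). Their member with the smallest p, Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane, stood at -0.57 ± 0.20. The 13 mitochondrially encoded genes had a median of -0.28, with -0.25 in number 1 and -0.31 in number 2, and were not called (adjusted p = 0.0674). They were called lower without WT 2 (adjusted p = 0.0033) and without ACC1 KO 1 (adjusted p = 2.7e-04). The median share of mitochondrial UMIs per iNKT cell was 3.09% in WT 1 and 2.503% in ACC1 KO 1, and 1.79% in WT 2 and 1.35% in ACC1 KO 2. The 33 nuclear genes of oxidative phosphorylation had a median of 0.064, with 0.21 in number 1 and -0.045 in number 2, and were not called (adjusted p = 0.0965). They were called higher without WT 2 (adjusted p = 4.3e-07) and without ACC1 KO 1 (0.0087) and lower without WT 1 (0.0026).

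The 28 measured G2/M genes had a median log2 fold change of 0.84, with 1.25 in number 1 and 0.62 in number 2, and the 26 S phase genes one of 0.32, with 0.50 and 0.17. In 20 G2/M members and 13 S phase members both ACC1 KO libraries lay above both WT libraries, and in none below. No member of either list passed when adjusted over the list alone. Aurkb, a mitotic kinase, stood at 0.98 ± 0.31 (SE), Cks2 at 0.57 ± 0.15, Uhrf1 at 0.73 ± 0.19 and Ccne2, cyclin E2, at 0.58 ± 0.18. Camera called both lists higher (adjusted p = 7.5e-17 for G2/M and 2.1e-08 for S phase), and neither with an estimated correlation (adjusted p = 0.497 with an estimated correlation for each). When every library was given the same mix of iNKT classes, the S phase list turned to lower (adjusted p = 0.0807) and Uhrf1 to -0.017, while G2/M stayed called higher (adjusted p = 0.0011).

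Of the remaining lists, glucocorticoid response genes had a median log2 fold change of 0.37 over 13 members, with 0.45 in number 1 and 0.33 in number 2. Adjusted over the list alone, 1 member rose, Pik3ip1, an inhibitor of PI3 kinase, at 1.07 ± 0.19 (SE), and Tsc22d3, which encodes GILZ, stood at 0.78 ± 0.20. Type I interferon response genes had a median of 0.13 over 33 members, with 0.28 in number 1 and 0.051 in number 2. None passed over the list alone, 11 lay higher and 2 lower without overlap, and Oasl2 stood at 0.69 ± 0.17. Among 18 glycolysis genes 1 rose over the list alone, hexokinase 2 (Hk2), at 1.63 ± 0.24, and the median was 0.11. Among 23 mTORC1 and HIF1 targets 1 rose, the aldolase Aldoc, at 2.51 ± 0.29, and the median was 0.094. The 24 p53 targets had a median of 0.11 and none passed over the list alone. The 12 heat shock genes, which mark cell handling, had a median of 0.26 and none passed. Camera called all 6 lists higher, with adjusted p of 4.8e-04 for glucocorticoid response, 0.0015 for interferon, 0.036 for glycolysis, 0.0098 for mTORC1 and HIF1, 0.0064 for p53 and 0.0136 for heat shock. None was called with an estimated correlation, where the adjusted p was 0.482 for glucocorticoid response and 0.497 for each of the other 5. The interferon call was also lost without ACC1 KO 1 (adjusted p = 0.353). The p53 call was lost without ACC1 KO 1 (0.123) and without WT 2 (0.057), and that of mTORC1 and HIF1 without WT 2 (0.169) and without ACC1 KO 1 (0.0571). The calls of glycolysis and heat shock were lost without WT 1 (0.485 and 0.942), without ACC1 KO 2 (0.729 and 0.878) and with the same mix of classes (0.193 and 0.0763).

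**Figure D2:**
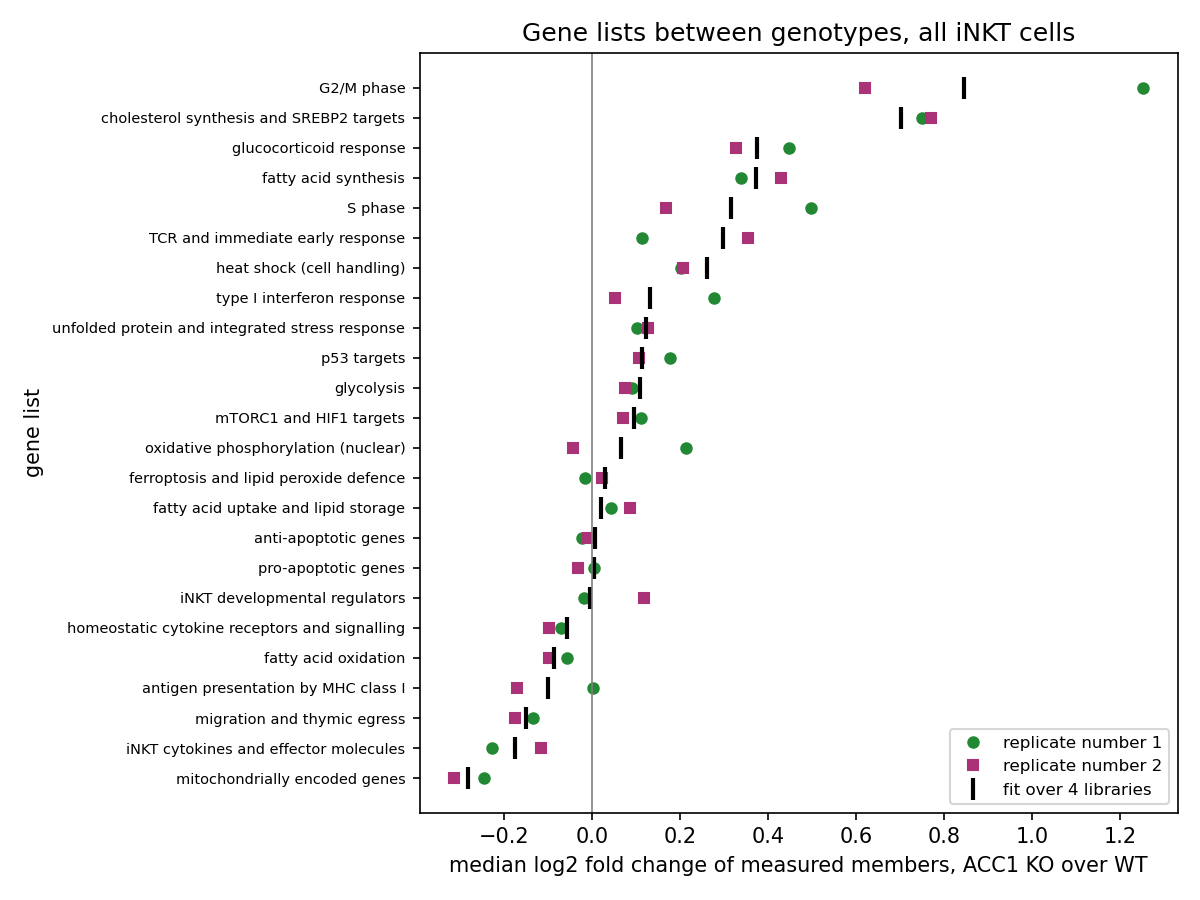
Median log2 fold change, ACC1 KO over WT, of the measured members of each gene list in all iNKT cells. Green circles are the libraries numbered 1, purple squares those numbered 2, and black bars the fit over the 4 libraries; the cholesterol list lies at 0.70 to 0.77 in all 3, the G2/M list spreads from 0.62 to 1.25, and the pro-apoptotic and anti-apoptotic lists lie near 0.

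The p53 target list, called higher by camera above, also holds Pmaip1 and Bbc3 and so bears on cell survival. The lists of apoptosis, ferroptosis and stress response genes were not called over the 4 libraries. The 24 pro-apoptotic genes had a median log2 fold change of 0.0043, with 0.0034 in number 1 and -0.033 in number 2 (camera adjusted p = 0.755). Their 2 members with the smallest p encode BH3-only proteins: Pmaip1, which encodes NOXA, stood at 1.46 ± 0.39 (SE) and Bbc3, which encodes PUMA, at 0.99 ± 0.28. Both were higher in both ACC1 KO libraries but failed adjustment over the list alone and over all genes (edgeR adjusted p = 0.772 and 0.815). Without ACC1 KO 2 the list was called higher (adjusted p = 0.0244). The 17 anti-apoptotic genes had a median of 0.0067 (adjusted p = 0.714). Bcl2 went from 511 ± 107 to 745 ± 223 CPM, a log2 fold change of 0.54 ± 0.28, and Bcl2a1a, whose reads cannot be told from those of near-identical copies, lay under 1 CPM in both genotypes. The 24 genes of ferroptosis and lipid peroxide defence had a median of 0.027 (adjusted p = 0.169). Lpcat3, which inserts polyunsaturated fatty acids into phospholipids, stood at 0.74 ± 0.13, and Acsl4 at 0.41 ± 0.13. The 33 genes of the unfolded protein and integrated stress response had a median of 0.12 (adjusted p = 0.0573) and were called higher without WT 2 (0.0062) and without ACC1 KO 1 (0.0366). Psat1, an enzyme of serine synthesis, stood at 0.51 ± 0.15 there.

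Effector and migration genes went both ways. Of 17 measured cytokine and effector genes, 1 rose and 1 fell when adjusted over the list alone. Granzyme B, Gzmb, went from 292 ± 21.8 to 504 ± 36.0 CPM, a log2 fold change of 0.79 ± 0.16 (SE), and Il2 went from 2.90 ± 0.211 to 1.10 ± 0.2504 CPM, at -1.38 ± 0.29. The list was not called (camera adjusted p = 0.387), but was called lower without WT 1 (0.0038) and without ACC1 KO 2 (0.0244). Of 22 migration and egress genes, 3 rose and 3 fell over the list alone. The integrin Itga4 fell by 1.30 ± 0.19 and the chemokine receptors Cxcr6 and Cxcr3 fell by 0.57 ± 0.15 and 0.49 ± 0.12. The list was not called (adjusted p = 0.387) and was called lower with the same mix of classes (0.0299). The 34 developmental regulators had a median of -0.0062, opposite in sign to their test (adjusted p = 0.104, higher), and were called higher without WT 1 (0.0018) and without ACC1 KO 1 (0.048). The methyltransferase gene Ezh2 stood at 0.66 ± 0.15. TCR and immediate early genes had a median of 0.30 over 26 members (adjusted p = 0.0599), with Tnfaip3 at 0.54 ± 0.18. They were called higher without WT 2 (0.0067), without ACC1 KO 1 (2.4e-05) and with the same mix of classes (0.0197). The homeostatic cytokine receptors (median -0.059, adjusted p = 0.169, and 0.0397 without WT 2) and MHC class I presentation (median -0.10, adjusted p = 0.113) were not called.

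The sample checks gave the following. Sex-linked genes did not separate the genotypes (camera adjusted p = 0.890). That list was called lower without WT 2 (6.7e-04) and higher without ACC1 KO 2 (0.0069), where the sexes are no longer balanced. The long non-coding RNAs read for RNA quality had a median log2 fold change of 0.27 (adjusted p = 0.512), and Malat1 took 15628, 13630, 14040 and 13162 CPM in WT 1, WT 2, ACC1 KO 1 and ACC1 KO 2. The T cell receptor segments of iNKT cells had a median of 0.0085 (adjusted p = 0.387, direction of the test lower), with Trac at -0.33 ± 0.16 (SE). Clusters of other cell types, removed before the sums, held 11.7% of the kept cells in WT 1 and 5.78% in ACC1 KO 1, and 1.03% in WT 2 and 2.04% in ACC1 KO 2. Igkc, an immunoglobulin transcript of B cells, remained at 10.3, 0.697, 166 and 1.22 CPM in the iNKT sums of WT 1, WT 2, ACC1 KO 1 and ACC1 KO 2.

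The next comparison was of the shares of iNKT classes, named from fixed markers. In the libraries labelled ACC1 KO, iNKT2-like cells, marked by Zbtb16 and Plac8, held 6.52% and 6.33% of iNKT cells, against 3.64% and 2.34% in the WT libraries, a ratio of means of 2.15 with 1.79 in number 1 and 2.71 in number 2. Cycling cells held 5.17% and 6.72% against 2.17% and 4.203% (ratio 1.87, with 2.38 and 1.60, and 2.74 without WT 2). Cells marked by the interleukin-17 programme, iNKT17-like, held 0.392% (22 cells) and 0.410% (32 cells) against 1.74% (80 cells) and 0.876% (79 cells), a ratio of 0.307 with 0.226 and 0.468. iNKT1-like cells held 75.7% and 76.3% against 83.3% and 84.2% (ratio 0.908), and interferon-responding cells 9.93% and 8.97% against 7.63% and 7.91% (ratio 1.22). In these 5 classes the genotypes did not overlap, and the exact two-sided permutation test gave p = 0.3333, the smallest it can give. iNKT0-like cells, the earliest stage, held 2.26% and 1.24% against 1.56% and 0.510% and overlapped (ratio 1.69, and 3.44 without WT 1 and 1.12 without WT 2). For iNKT17-like cells the 95% Clopper-Pearson intervals, which cover counting error only, were 1.38 to 2.15% and 0.694 to 1.09% in the WT libraries and 0.246 to 0.593% and 0.281 to 0.579% in the ACC1 KO libraries. The order of the genotypes for iNKT2-like, iNKT17-like and interferon-responding cells was the same when 519 genes with an unadjusted p under 0.05 between genotypes in iNKT1-like cells were left out of the clustering, with ratios of 2.17, 0.318 and 1.23. In that setting a cluster led by the replication genes Hells and Mcm3 was named iNKT1-like, so that cycling and iNKT1-like cells are not compared there. When each cell was instead named by its highest marker mean, the genotypes overlapped for iNKT2-like cells (ratio 0.995, with 0.827 in number 1 and 1.28 in number 2), and the iNKT17-like ratio was 0.735. Interferon-responding cells overlapped under that naming too, at 16.6% and 19.7% in the ACC1 KO against 13.4% and 18.4% in the WT libraries. When clusters came from the WT libraries alone, the genotypes overlapped for interferon-responding cells (ratio 0.981, with 1.02 in number 1 and 0.941 in number 2). Those clusters, and clusters at resolution 0.5, held no iNKT2-like class. Shares are of sorted cells, so that they say nothing about cell numbers in the thymus.

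**Figure D3:**
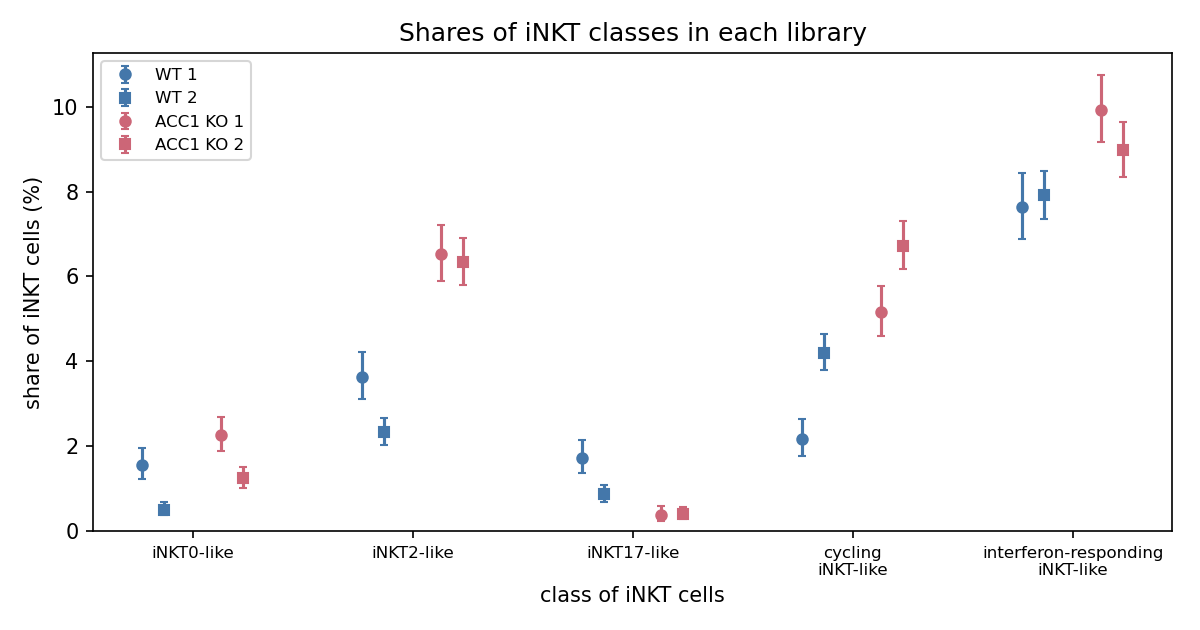
Share of iNKT cells (%) in each class and library, with exact (Clopper-Pearson) 95% intervals as bars. Circles are libraries numbered 1, squares those numbered 2, blue is WT and red is ACC1 KO, and iNKT1-like cells (75.7% to 84.2%) are not drawn; red points lie above blue points for iNKT2-like, cycling and interferon-responding cells, below them for iNKT17-like cells, and overlap them for iNKT0-like cells.

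The genotype comparison was repeated within each class that had at least 50 cells in every library, which left out iNKT17-like (22 cells in ACC1 KO 1) and iNKT0-like cells (46 cells in WT 2). In iNKT1-like cells Scd1 was the 1 gene of 13683 called (adjusted p = 0.0222, edgeR quasi-likelihood test). It had 1 UMI in the WT and 889 UMIs in the ACC1 KO libraries, a ratio of 937 (95% counting interval, 168 to 37045). In cycling cells 4 of 10815 genes were called, all higher. They were Scd2, from 59.1 ± 11.8 to 298 ± 22.98 CPM (log2 fold change 2.38 ± 0.21, SE, adjusted p = 0.0020), Srebf1 (1.83 ± 0.21, adjusted p = 0.0095), Fads2 (1 against 197 UMIs, adjusted p = 0.0020) and Scd1 (1 against 159 UMIs, adjusted p = 0.015). In interferon-responding cells 5 of 10204 genes were called, all higher. Among them were Scd2 (2.74 ± 0.24, adjusted p = 0.0089), Srebf1 (1.89 ± 0.22), Acsl3 (2.43 ± 0.28) and Scd1 (1 against 103 UMIs), the last 3 each at an adjusted p of 0.0306. In iNKT2-like cells edgeR called none of 10452 genes, and DESeq2 called 3. In edgeR 242 genes had an unadjusted p under 0.05, a smaller share than chance alone gives. DESeq2 called 86 genes in iNKT1-like, 8 in cycling and 16 in interferon-responding cells. Fads2 had 0 UMIs in the WT iNKT1-like cells and 200 in the ACC1 KO ones, at least 70.3-fold higher against a floor of 3 counts over the WT libraries, where the 95% counting interval of the ratio starts at 56.6. The counts of calls were larger in every class with the replicate number as a block, and moved with the libraries used. Without WT 1, WT 2, ACC1 KO 1 and ACC1 KO 2 in turn, 4, 2, 11 and 12 genes passed in iNKT1-like cells, 7, 2, 29 and 5 in iNKT2-like, 11, 9, 52 and 52 in cycling and 23, 14, 56 and 39 in interferon-responding cells. With the libraries thinned to the smallest total, 0, 2 and 2 genes passed in iNKT1-like, cycling and interferon-responding cells, with the same number of cells 0, 7 and 1, and among genes of at least 10 CPM, which leaves out Scd1 in iNKT1-like cells, 0, 2 and 3. The largest iNKT1-like cluster was led by Atp8a2 and Cd226 in both WT libraries, by Gm4208 and Ccl5 in ACC1 KO 1 and by Sidt1 and Fgf13 in ACC1 KO 2.

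The lipid lists rose in each of these 4 classes. Adjusted over the list alone, 18 of 25 cholesterol and SREBP2 genes rose in iNKT1-like cells, 10 of 24 in iNKT2-like, 13 of 24 in cycling and 13 of 24 in interferon-responding cells, and none fell. The medians were 0.78, 0.56, 0.66 and 0.79. Camera called the list in all 4 classes, and in none with an estimated correlation (adjusted p = 0.213, 0.273, 0.199 and 0.200 with an estimated correlation). The test with an estimated correlation had little room to pass on 4 libraries. For fatty acid synthesis 10 of 20, 4 of 18, 7 of 20 and 9 of 18 members rose over the list alone, with medians of 0.60, 0.57, 0.54 and 0.60. That list too was called in all 4 classes, and in none with an estimated correlation (adjusted p = 0.309, 0.508, 0.217 and 0.243). In iNKT2-like cells the S phase, G2/M and interferon lists were called lower, with medians of -0.41, -0.39 and -0.28 (adjusted p = 4.8e-16, 6.0e-06 and 7.2e-07, and 0.508 for each with an estimated correlation). In numbers 1 and 2 these medians were -0.19 and -0.64 for S phase, -0.52 and -0.17 for G2/M and -0.046 and -0.41 for interferon. The iNKT2-like cluster itself scored 2.02 for the cycling markers, above the limit of 1.5 used to name cycling cells, so that the S phase and G2/M values may also reflect how many dividing cells it held. The other classes went the other way where these lists were called. G2/M was called higher in iNKT1-like cells, with a median of 0.33, 0.35 in number 1 and 0.30 in number 2 (adjusted p = 2.5e-04, and 0.451 with an estimated correlation), and in cycling cells, with 0.24, 0.51 and 0.12 (adjusted p = 2.1e-07, and 0.674 with an estimated correlation). The interferon list was called higher in cycling cells, with a median of 0.38, 0.81 in number 1 and 0.22 in number 2 (adjusted p = 6.7e-12, and 0.217 with an estimated correlation), in iNKT1-like cells, with 0.14, 0.23 and -0.0091 (adjusted p = 0.0316, and 0.565 with an estimated correlation), and in interferon-responding cells, with 0.10, 0.076 and 0.14 (adjusted p = 0.0076, and 0.452 with an estimated correlation). S phase was called in none of these 3 classes (adjusted p = 0.223 in iNKT1-like, 0.767 in cycling and 0.825 in interferon-responding cells).

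The last comparison asked whether the genotype effect differed between iNKT2-like and iNKT1-like cells, with the library as a block. The difference was positive in 11 and negative in 17 of 13385 genes (edgeR quasi-likelihood test, 892 at an unadjusted p under 0.05). Scd2 had the smallest p (the 3 genes named here were chosen after their values were seen). Its log2 fold change, fitted in each class alone, was 3.11 in iNKT1-like and 1.37 in iNKT2-like cells, and the joint fit gave a difference of -1.74 ± 0.15 (SE, adjusted p = 2.4e-11). Among other gene list members, the cholesterol synthesis gene Fdps had 1.71 and 0.71 (adjusted p of the difference 0.0029) and Hk2 had 1.96 and 0.41 (5.2e-04). Without WT 1, WT 2, ACC1 KO 1 and ACC1 KO 2 in turn, 80, 53, 120 and 49 genes passed, and 6 passed among genes with a mean of at least 10 CPM.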

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

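A test of the difference itself picked out 28 genes whose genotype effect differed between iNKT2-like and iNKT1-like cells. The difference in log2 fold change, iNKT2-like minus iNKT1-like, was -0.99 for Fdps, -1.53 for Hk2, -0.76 for Ddit4, -1.91 for Gzma, -1.70 for Ifit3b and -1.74 for Scd2, the members of the fixed gene lists among them. Fitted in each class alone, Gzma stood at 0.86 in iNKT1-like and -1.08 in iNKT2-like cells and the interferon-induced Ifit3b at 0.75 and -0.99. The differences are therefore not exactly those of the joint fit above, and these names were chosen after their values were seen. Gzma is a fixed marker of iNKT1-like cells and Ifit3b of interferon-responding cells. Their values in the iNKT2-like cluster may thus also reflect how many such cells it held, which was not tested.

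Cells that no comparison used, the clusters of DP thymocyte-like cells, held 2 of the 5 transcripts given here above the level of the WT libraries. The ratio of mean CPM, ACC1 KO over WT, was 2.70 for Fads2 (5, 3, 22 and 12 UMIs in WT 1, WT 2, ACC1 KO 1 and ACC1 KO 2) and 1.57 for Acaca, with both ACC1 KO libraries above both WT libraries. It was 1.01 for Scd2, 0.917 for Srebf1 and 0.404 for Scd1, which were not higher in both. Scd1 had 2, 0, 1 and 0 UMIs in the same order, too few for its ratio to be read. The 5 genes were chosen after their values were seen and no explanation was tested for them.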

How the results depend on the processing

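Of the single gene lists, 185 results kept their direction and side of the threshold, 32 lost the call, 23 gained one and 3 reversed; of named genes 632 kept, 81 gained a call and 22 reversed. Shares kept 67, moved 16 and reversed 2. Counts of calls moved in 13 of 22 settings for all cells, 45 of 63 for classes and 5 of 6 for the class difference. Sums of all cells thinned to the smallest total still gave 1 gene. Except where construction is named, the cause was not tested.

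Counts of genes passing are given in the order all cells, iNKT1-like, iNKT2-like, cycling, interferon-responding. They were 102, 86, 3, 8 and 16 with the DESeq2 Wald test and 229, 228, 24, 50 and 79 with no filter on low counts. With a mean of at least 10 CPM, which tests fewer genes, they were 0 for all cells, 0 for iNKT1-like, 2 for cycling and 3 for interferon-responding cells, and 6 for the class difference. With every barcode 0 passed for all cells. Sums thinned to the smallest total gave 0, 2 and 2 for iNKT1-like, cycling and interferon-responding cells, and the same number of cells 0, 7 and 1. Leaving out each library gave 2 to 12, 2 to 12, 2 to 29, 9 to 52 and 14 to 56, and 49 to 120 for the class difference.

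With the replicate number as a block, counts were 1162, 1351, 100, 192 and 306, Acaca passed at a log2 fold change of 0.75, and lists gained calls: oxidative phosphorylation (adjusted p = 0.0359), mitochondrially encoded (0.0018), unfolded protein response (0.0049), TCR and immediate early (4.9e-05) and MHC class I (0.0463). For all cells, iNKT1-like and iNKT2-like cells, the block gave 1307, 1412 and 92 with limma-voom, 437, 341 and 6 with DESeq2, 1059, 1329 and 108 without the robust spread, and 1162, 1351 and 100 with the legacy estimate, settings added after the data were seen. Libraries of the same number deviated together (correlation 0.695). They shared sex and depth, but the labels do not pair them, and 2 pairs cannot settle whether they shared a batch or day. The main tests used no block by number, so the difference in sex and depth stayed in their spread. The few calls of edgeR without a block, and Acaca not passing in it, depend on that choice.

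An estimated correlation left 0 lists called (adjusted p 0.158 for cholesterol, 0.482 for fatty acid synthesis and glucocorticoid response, 0.497 for uptake, glycolysis, p53, heat shock, S phase, G2/M, interferon and mTORC1). That version tests on the few degrees of freedom of 4 libraries, so a lost call alone does not show that members were correlated. Fry left 1, cholesterol, with fatty acid synthesis at 0.0876, uptake 0.0877, glucocorticoid 0.0648, mTORC1 0.205, glycolysis 0.777, heat shock 0.840, and p53, S phase, G2/M and interferon at 0.527. With the same mix of classes S phase reversed (0.0807), as did Uhrf1 (-0.0172) and Id3 (-0.0626); glycolysis (0.193) and heat shock (0.0763) lost their calls, and oxidation (0.0197), TCR and immediate early (0.0197) and migration (0.0299) gained one.

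Leaving out each library, adjusted p ran from 0.0017 to 0.729 for glycolysis, 4.3e-07 to 0.914 for oxidative phosphorylation, 2.7e-04 to 0.903 for mitochondrially encoded genes, 0.0244 to 0.834 for pro-apoptotic genes, 3.0e-04 to 0.123 for p53, 0.0062 to 0.612 for unfolded protein response, 2.4e-05 to 0.635 for TCR and immediate early genes, 1.2e-04 to 0.942 for heat shock, 7.7e-06 to 0.353 for interferon, 0.0038 to 0.476 for cytokines, 0.0397 to 0.934 for homeostatic receptors, 0.0018 to 0.967 for developmental regulators, 0.0026 to 0.169 for mTORC1 and 6.7e-04 to 0.931 for sex-linked genes. Log2 fold changes that reversed ran from -0.00999 to 0.34 for Cox7a2, -0.29 to 1.20 for Bag3, -0.13 to 0.59 for Kcnq1ot1, -0.22 to 0.86 for Neat1, -1.30 to 4.33 for Meg3, -1.35 to 1.503 for the gene Gm42418, -0.616 to 0.0203 for gene Trav11, -0.659 to 0.0977 for gene Traj18 and -0.13 to 0.50 for Trbv1. Those of gene Tsix (-6.45 to 6.64), Xist (-10.23 to 9.21), gene Eif2s3y (-14.298 to 14.187) and gene Uty (-13.772 to 10.848) follow from the sexes being left unbalanced.

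The ratio of iNKT1-like shares was 0.921 at resolution 0.5, 0.905 at resolution 2, 0.954 from clusters of the WT libraries alone, 0.891 by highest marker, 0.912 scaled together, 0.923 without genotype genes, 0.935 among non-cycling cells and 0.903 to 0.913 leaving out each library. By highest marker it was 1.14 for iNKT0-like, 0.995 for iNKT2-like cells, where the genotypes overlapped (0.827 in number 1 and 1.28 in number 2), and 0.735 for iNKT17-like cells. For interferon-responding cells it was 1.14 by highest marker, where the genotypes overlapped as well. The interferon-responding ratio was 0.981 with clusters from the WT libraries alone, where the genotypes overlapped. The 0.995 for iNKT2-like and the 0.981 for interferon-responding cells are the 2 counted as reversed above, by the side of 1 alone. Leaving out each library gave 1.12 to 3.44 for iNKT0-like and 1.41 to 2.74 for cycling cells. At resolution 0.5 and with WT clusters, iNKT0-like and iNKT2-like cells gave no value, and 79.8% of the cells of 1 WT cluster named cycling lay in the iNKT2-like cluster of the report. This cluster and 2 WT clusters named iNKT1-like had more markers of another class than of their own among their top 10 genes, so that the names cycling and iNKT1-like, and the 0.954 above, do not hold there. Without genotype genes 1 iNKT1-like cluster of 61 cells failed the same way and a cluster led by Hells and Mcm3 took the iNKT1-like name, which limits the 0.923. The iNKT17-like class difference was not run.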

Other observations

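An iNKT1-like cluster held a lower share of iNKT cells in both libraries labelled ACC1 KO. When the 519 genes with an unadjusted p under 0.05 between genotypes in iNKT1-like cells were left out of the clustering, a setting chosen after the data were seen, an iNKT1-like cluster high in Atp8a2 and Cd226 held 37.4% of iNKT cells in WT 1 and 18.8% in WT 2, against 14.5% in ACC1 KO 1 and 9.28% in ACC1 KO 2. The exact two-sided permutation test gave p = 0.3333, the smallest it can give, and 4 of the 7 iNKT1-like clusters of this setting overlapped between genotypes, while 2 held higher shares in both ACC1 KO libraries. The 2 genes name the cluster and were chosen after its values were seen.

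The tests below of class mix, of RNA from other cells and of Trdc with Trac were chosen after the results were seen, and the other 3 before. That of RNA from other cells replaced one built on the shares of those cells, which could not tell how much RNA they brought.

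For the higher cholesterol and fatty acid synthesis genes, a change in the mix of classes would have lowered the median log2 fold change of their 46 members to under 50% of its value. It was 0.61 with the same mix and 0.63 without, which speaks against that cause. RNA of B cell-like, DP thymocyte-like and myeloid-like cells, read from the median level of their abundant markers in the iNKT sums, accounts for a median part of 0.0133 of the rise in number 1 and 0.00368 in number 2, over the 40 members higher in both, which speaks against it. That median does not follow single genes: Igkc went from 10.3 CPM in WT to 166 CPM in ACC1 KO in number 1 and from 0.697 to 1.22 CPM in number 2, with Cd79a at 0.849 and 0.841 CPM, and 0.523 and 0.551 CPM. A joint rise of liver X receptor targets, a biological candidate explanation for Abca1 and Abcg1, was left open: 2 of 4 targets (Mylip at 0.06 and Arl4c at 0.18) were higher in both numbers, while Smpdl3a stood at -0.26 and Nr1h3 at 0.11 ± 0.43 (SE), with -0.30 in number 1 and 0.36 in number 2.

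For the lower share of iNKT17-like cells no biological explanation was tested, and loss by renaming would have left the summed CPM of the class markers, over every barcode, at 0.8 of WT or more. The ratios were 0.40 in number 1 and 0.588 in number 2, against renaming of cells that kept their marker level. Cells renamed because their markers were lower would lower the sum as well, so that the ratios cannot speak to them. Whether the class holds iNKT cells could not be told from the invariant chain segments Trav11, Trav11d and Traj18, which stood at 0.286 of their level in iNKT1-like cells on 7 UMIs. Trdc at 0 UMIs and Trac at 0.879 of its level in iNKT1-like cells speak against gamma-delta T cells as the whole class. The gamma constant genes Tcrg-C1, Tcrg-C2 and Tcrg-C4 go the other way, at 775 CPM against 245 CPM in iNKT1-like cells, so that such cells as a part of the class stay open.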
